A study of Mus musculus with 6 samples.

How the data were processed

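Gene expression had been measured in mouse bone marrow cells with 6 Affymetrix mouse arrays of the Mouse430_2 type, 2 for each of 3 groups. Per the labels, the MN1 and MN1VP16 groups held GFP-positive marrow cells carrying the retroviral vector pSF91-MN1-IRES-GFP or pSF91-MN1VP16-IRES-GFP, and the Gr1Mac group held marrow cells sorted for Gr1 and CD11b. Per the labels' protocols, RNA was extracted with TRIZOL and labelled with a 3' IVT kit, in which copying starts at the poly(A) tail, so the probes read the 3' end of a transcript.

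The deposited table held log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes; the version was not given in the sources used here. RMA subtracts background, quantile-normalises the arrays and summarises the probes of a set, so differences of dim genes are compressed and a change in total RNA per cell cannot be seen. The values of an array had a median between 5.36 and 5.43 log2 units. No detection calls and no scanner intensities were used here, so a probe set near the bottom of the scale has no stated background. As a guide chosen after the values were seen, Y-linked genes on the Xist-high arrays read at most 4.05, and Xist on the Y-high arrays between 5.53 and 5.84. For arrays, the number of replicates limits the precision.

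The table had 45101 lines, of which 64 were control features and 45037 ordinary probe sets. GEO's platform annotation named exactly 1 gene for 34945 probe sets, several genes for 932 and none for 9160. The last 2 kinds were left out of the gene-level tests. Symbols were checked through the gene number against a RefSeq gene table (GRCm38.p6, used for names only), which matched 34741 probe sets and changed 0 symbols. Neither the labels nor the table named a genome build, so no coordinates are given. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Among the called genes that the rule below selected, 0 had another probe set called in the opposite direction.

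Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 6 arrays with the group as the only term, which left 3 residual degrees of freedom and added 3.03 from the prior. The contrasts were MN1 minus Gr1Mac, MN1VP16 minus Gr1Mac and MN1VP16 minus MN1. The p-values were adjusted over the 18193 genes by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. Differences are group means of log2 values with limma's standard error (SE). Folds are 2 to the power of the difference, with 95% intervals from the same moderated statistic. Where the dimmer group's mean was at or under 5.84 log2 units, a called gene's fold is written as at least the brighter group's mean over the mean, across the dimmer group's arrays, of the higher of 5.84 and the array's own reading. The labels do not say that the arrays of a group came from separate mice, so p-values measure only the spread between these arrays, which may be technical. With 2 arrays in a group, no exact permutation test can fall below 0.05, and no other splits of the arrays were counted.

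The design, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. There were 23 gene lists with 533 entries: the HoxA-Meis1 programme, stem and progenitor markers, primary granule genes, secondary and tertiary granule genes, mature neutrophil genes, monocyte and macrophage genes, MHC class II presentation genes, interferon response genes, chemokine and cytokine genes, myeloid transcription factors, retinoid signalling genes, cell cycle genes, nucleolar and Myc target genes, p53 target and senescence genes, cholesterol synthesis genes, immediate early and heat shock genes, and markers of erythroid cells, B cells, T and NK cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, dendritic cells, and stroma with endothelium. They covered 514 distinct genes, of which 463 were measured and 51 were not named by a single-gene probe set. A list was compared with all other genes by camera with an inter-gene correlation of 0.01, and beside it by camera with an estimated correlation and by fry, which asks only whether the list's own genes move one way on balance. Camera with an estimated correlation tests on the 3 residual degrees of freedom, so hardly any list could pass it. For stem and progenitor markers in MN1 minus Gr1Mac the estimate was -0.0121, under 0.01, yet camera's adjusted p rose from 9.43e-11 to 0.116. For secondary and tertiary granule genes the estimate was 0.898, far above 0.01. Not passing thus neither shows nor excludes that correlation between genes made a call. List p-values were adjusted over the 23 lists within a contrast. Member counts are given over all genes and adjusted over the list alone.

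Named genes followed a fixed rule. It took Mn1, Irf8, Hoxa9, Meis1, Kit, Cd34, Flt3, Cebpa, Myc and Itgam, and in each contrast the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups, leaving out predicted genes and immunoglobulin or T cell receptor segments. From each list it took the 2 called genes with the largest rise and the 2 with the largest fall, or, where none was called, the 2 with the smallest p. Where a count was 5 or fewer, all its genes could be named. Cebpe, Ly6g, Ly6c1 and Ly6c2 were also in the rule but had no single-gene probe set. Itgam encodes CD11b, which was part of the sort of the Gr1Mac cells, so its difference from that group is no finding. Genes named outside the rule are said to be so.

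The alternatives were a fit on only the 2 groups of a contrast, the replicate number as a block, an intensity trend or a robust estimate in the variance prior, quantile normalisation or median centring of the deposited values, leaving out the dimmest 40% of genes or genes whose highest group mean was under the median, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets marked _x_at, _s_at or _a_at, an adjusted p under 0.01, a fold of at least 2, camera with an estimated correlation, fry, and leaving out each array in turn. After the data were seen, 2 blocks were added: a split of the arrays in the control features, and the sex read from Xist and Y-linked genes.

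The fitting code was tested on simulated data with the arrays' own means and spreads over 18193 genes. Of 67 genes changed 2-fold, 32.8% were called in MN1 minus Gr1Mac, 22.4% in MN1VP16 minus Gr1Mac and 31.3% in MN1VP16 minus MN1. Of 67 genes changed 4-fold, 94.0%, 100% and 92.5% were called in these contrasts, and all of the 66 genes changed 16-fold. Calls on unchanged genes numbered 13, 12 and 7, and 0 of 20 unchanged lists was called in any of the 3. The simulated genes varied independently and these lists were drawn at random. The 0 thus says nothing on false calls of lists whose genes vary together. A change of 2-fold was missed more often than found in this simulation, in which few genes changed. The adjusted p threshold is easier to pass where many genes change, as in MN1 minus Gr1Mac, so these shares do not carry over to that contrast. Figures were drawn with matplotlib 3.10.9.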

Results

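Expression was profiled in mouse marrow cells transduced with a vector for MN1, a transcriptional cofactor whose overexpression causes myeloid leukaemia in transplanted mice, or a construct named MN1VP16. VP16 is the name of a herpesvirus transcriptional activator; the labels describe the construct no further. Per the labels, marrow of C57BL/6J donors given 150 mg/kg 5-fluorouracil for 4 days was stimulated for 48 hours with cytokines, transduced by culture with virus-producing cells and transplanted into lethally irradiated syngeneic mice. GFP-positive marrow cells were sorted 4 weeks later, giving the groups MN1 (n = 2 arrays) and MN1VP16 (n = 2). The group called Gr1Mac (n = 2) held marrow cells positive for Gr1 and CD11b, surface markers of granulocytes and monocytes, and whether these came from transplanted mice is not said. The values were the authors' log2 RMA values per probe set.

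Arrays of one group resembled each other most. Across probe sets, the correlation was 0.990 between the MN1 arrays, 0.981 between the MN1VP16 arrays and 0.982 between the Gr1Mac arrays. It ranged from 0.949 to 0.972 between MN1 and MN1VP16, from 0.953 to 0.963 between MN1VP16 and Gr1Mac, and from 0.890 to 0.927 between MN1 and Gr1Mac. The first principal component held 72.5% of the variance, with MN1 at one end, Gr1Mac at the other and MN1VP16 between them.

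The arrays also differed in the sex of the cells, which the labels do not give. Xist, the RNA that silences an X chromosome in female cells, lay at 12.36 and 12.59 log2 units on the MN1 arrays, at 5.53 and 5.84 on the MN1VP16 arrays, and at 10.44 and 5.83 on Gr1Mac arrays 1 and 2. The Y-linked gene Kdm5d lay at 3.01 and 3.20 in MN1, at 7.24 and 7.55 in MN1VP16, and at 3.11 and 7.37 on Gr1Mac arrays 1 and 2. Eif2s3y and Uty, also Y-linked, were high on the same 3 arrays as Kdm5d, with Eif2s3y at 10.40 and 7.43 in MN1VP16 and 10.51 on Gr1Mac array 2. Both MN1 arrays and Gr1Mac array 1 were thus high in Xist, and both MN1VP16 arrays and Gr1Mac array 2 were high in Y-linked genes. Every difference between MN1VP16 and MN1 below is also a difference between these patterns. These 4 genes were chosen after their values were seen.

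The only single-gene probe set for Mn1 was near the bottom of the scale on every array. It read 3.92 and 4.51 in MN1, 4.92 and 4.00 in MN1VP16, and 3.63 and 4.21 in Gr1Mac, and limma called it in no contrast (adjusted p = 0.621, 0.472 and 0.778). The labels give neither the species nor the ends of the inserted sequence, so this probe set does not check the labels.

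Readings of absent transcripts gave a guide to the background. On the Xist-high arrays the 3 Y-linked genes read at most 4.05 log2 units, and on the Y-high arrays Xist read up to 5.84. Background differs between probe sets, so a group mean at or under 5.84 can be background alone. For called genes with such a mean in the dimmer group, which numbered 1264, 265 and 209 in the 3 comparisons below, the fold is given as at least the ratio to that level, and their sizes have no order among themselves. For Fabp4, P2ry12, Cd209a, Perp and Eda2r, named below for their calls, both group means lay under it. This level was chosen after the values were seen.

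The first comparison asked how cells carrying the MN1 vector differed from Gr1-positive, CD11b-positive marrow cells. By camera, genes of blood stem cells, of the HoxA-Meis1 programme and of red cell precursors were higher as lists in MN1 cells. Genes of secondary and tertiary granules, mature neutrophils, monocytes and antigen presentation were lower as lists. None of these list calls held with an estimated correlation, a test that hardly any list could pass with 3 residual degrees of freedom. Fry called each of these lists except secondary and tertiary granule genes (fry adjusted p = 0.0666). Hoxa9, a homeobox gene of immature and leukaemic blood cells, lay at 12.54 ± 0.24 (SD, n = 2) log2 units in MN1 against 4.59 ± 0.60 in Gr1Mac, at least 105-fold higher (limma adjusted p = 0.00117). The surface marker Cd34 was at least 31.8-fold and the stem cell transcription factor Gata2 at least 66.3-fold higher, while the monocyte transcription factor Klf4 lay at 5.46 ± 0.14 in MN1 and 10.32 ± 0.66 in Gr1Mac, at least 22.4-fold lower. In all, limma called 3147 of 18193 genes higher and 2187 lower in MN1, of which 2428 and 1551 differed by at least 2-fold.

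Among stem and progenitor markers, 17 of 19 measured members rose and 0 fell, with the same numbers adjusted over the list alone. By fitted size the naming rule took Gata2 and Cd34, whose Gr1Mac means lay under 5.84 log2 units, so their rank rests on readings that can be background. Kit, the receptor for stem cell factor, was 5.72-fold higher, and the cytokine receptor Flt3 16.4-fold higher. The list stood above other genes (camera adjusted p = 9.43e-11, and adjusted p = 0.116 with an estimated correlation). In the HoxA-Meis1 programme, 6 of 11 members rose and 1 fell, again with the same numbers adjusted over the list alone (camera adjusted p = 0.0124, and 0.480 as the adjusted p with an estimated correlation). By fitted size the naming rule took Hoxa9 and Hoxa10, Hoxa10 at least 16.1-fold higher, and Meis1, the partner of Hoxa9, was at least 4.73-fold higher. All lay under 5.84 log2 units in Gr1Mac, so these sizes have no order. Hoxb4 was the member that fell, at least 2.84-fold lower. That list lost its call without Gr1Mac array 1 (camera adjusted p = 0.0919), without the dimmest 40% of genes (0.0597), without genes whose highest group mean was under the median (0.0930) and, narrowly, with the split of the control features described below as a block (0.0504).

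Of 17 measured erythroid markers, 14 rose and 0 fell (15 and 1 adjusted over the list alone). Car1, a red cell carbonic anhydrase, rose from 4.95 ± 0.32 to 13.53 ± 0.41, at least 207-fold higher, and the water channel Aqp1 was at least 42.3-fold higher. The erythroid shift had a camera adjusted p of 1.51e-08 and an adjusted p = 0.4999 with an estimated correlation. Nucleolar and Myc target genes, which serve ribosome building, rose in 28 of 29 members with 0 falls, likewise adjusted over the list alone (camera adjusted p = 1.44e-17, and adjusted p = 0.480 with an estimated correlation). Myc itself rose by 4.39 ± 0.31 log2 units (SE) and Cad, the enzyme that starts pyrimidine synthesis, by 4.21 ± 0.33. Cell cycle genes rose in 10 of 31 and fell in 1, the mitotic kinesin Kif23, with the same numbers adjusted over the list alone (camera adjusted p = 0.00306, and adjusted p = 0.773 with an estimated correlation). Their list lost its call without Gr1Mac array 2 or with sex as a block (camera adjusted p = 0.0508 in both), without the dimmest 40% of genes (0.0597) and without genes whose highest group mean was under the median (0.128). The replication licensing gene Mcm2 was 3.64-fold and its loader Cdc6 3.16-fold higher.

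Genes of mature myeloid cells moved the other way. Secondary and tertiary granule genes fell in 17 of 22 and rose in 0 (21 and 0 adjusted over the list alone), with Cd177 7.40-fold and Padi4, which citrullinates histones, 7.29-fold lower (camera adjusted p = 1.26e-07, and adjusted p = 0.550 with an estimated correlation). The mean of that list was 12.81 on MN1 array 1 and 11.77 on array 2, against 13.92 and 14.03 in Gr1Mac, so array 2 carried more of the fall. Mature neutrophil genes fell in 15 of 21 (18 adjusted over the list alone), where Ccl6 fell by 4.11 ± 0.53 and the cytokine Il1b fell by 3.84 ± 0.72 log2 units (camera adjusted p = 3.35e-06, and adjusted p = 0.4999 with an estimated correlation). The 2 neutrophil members that rose, also adjusted over the list alone, were the stefins Stfa3, an intracellular cathepsin inhibitor, by 4.48 ± 0.30, and Stfa2l1, by 2.32 ± 0.30. Primary granule genes were not called as a list (camera adjusted p = 0.275). Of these, 3 of 10 fell (Fcnb, Igsf6 and Serpinb1a) and 1, the chaperone Calr, rose, with the same numbers adjusted over the list alone. Without MN1 array 1 camera called the list lower (adjusted p = 0.0167).

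Monocyte and macrophage genes fell in 18 of 26 and rose in 1, the scavenger receptor Cd163 (20 and 1 adjusted over the list alone; camera adjusted p = 7.72e-08, and adjusted p = 0.4999 with an estimated correlation). Beside Klf4, cathepsin S, Ctss, fell by 3.45 log2 units. MHC class II presentation genes fell in 8 of 15 and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00285, and adjusted p = 0.4999 with an estimated correlation). The class II call was lost without probe sets marked _x_at, _s_at or _a_at (camera adjusted p = 0.0577). The class II chains H2-Aa and H2-Eb1 were 21.0-fold and 10.8-fold lower, and the members that rose, H2-Ob and H2-Oa, encode the chains of a modulator of peptide loading. Myeloid transcription factors fell in 15 of 25 and rose in 0 (16 and 0 adjusted over the list alone; camera adjusted p = 5.63e-07, and adjusted p = 0.480 with an estimated correlation), led by Junb and Cebpb, 12.8-fold and 11.9-fold lower. Immediate early and heat shock genes fell in 11 of 22 and rose in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00110, and adjusted p = 0.669 with an estimated correlation). Fos lay at 8.77 ± 0.08 in MN1 and 14.09 ± 0.05 in Gr1Mac, and the risers were the chaperones Hsph1 and Hsp90aa1. Interferon response genes fell in 5 of 32, namely Ifit3, Cmpk2, Oasl2, Oas3 and Ddx58, and in 0 adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.813 with an estimated correlation). The interferon call was lost without MN1 array 1 (camera adjusted p = 0.0704) or Gr1Mac array 1 (0.556), and without probe sets marked _x_at, _s_at or _a_at (0.116). With the split of the control features described at the end of this comparison as a block, the interferon list turned upwards (0.262 by camera) and the immediate early call was lost (0.583).

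The remaining lists were not called by camera in this comparison, and their members moved both ways. Mast cell, basophil and eosinophil markers rose in 5 of 19 and fell in 1 (5 and 2 adjusted over the list alone), with the mast cell protease Cpa3 at least 152-fold and the IgE receptor chain Ms4a2 137-fold higher and Alox15 at least 4.64-fold lower. Megakaryocyte and platelet markers rose in 5 of 18 and fell in 4, with the thrombin receptor F2r at least 186-fold higher and Clec1b at least 6.56-fold lower. P53 target and senescence genes rose in 8 of 21 and fell in 7 (8 and 8 adjusted over the list alone), with Zmat3 at least 10.6-fold and the cell cycle inhibitor Cdkn2b 18.5-fold higher and the death receptor Fas at least 3.43-fold lower. Cholesterol synthesis genes fell in 6 of 20, led by Msmo1 and Hsd17b7, and rose in 2, Dhcr7 and Lss. Dendritic cell markers rose in 6 of 19 and fell in 4, B cell markers rose in 4 of 21 and fell in 2, and chemokine and cytokine genes rose in 2 of 24 (Il6 and Ccl17) and fell in 5 (7 adjusted over the list alone), with Cxcl2 at least 26.8-fold lower. T and NK cell markers rose in 2 of 20 (Il7r and Lat) and fell in 1 (Cd3d). Retinoid signalling genes rose in 1 of 18 (Nrip1) and fell in 2, Rarg and Dhrs3 (1 adjusted over the list alone), and stromal and endothelial markers rose in 1 of 21 (Plvap) and fell in 3, Acta2, Fabp4 and Sparc (1 adjusted over the list alone). Where no number is given here, that adjusted over the list alone was the same. The lowest camera adjusted p of these lists was 0.157; cholesterol synthesis genes were called lower without Gr1Mac array 2 (camera adjusted p = 0.00798), and chemokine and cytokine genes without the dimmest 40% of genes (0.0127). Without genes whose highest group mean was under the median, camera also called chemokine and cytokine genes lower (adjusted p = 0.0297). Fry called the chemokine and cytokine list (adjusted p = 0.0316) and the retinoid list (0.0260) lower. Of the lists that camera called in this comparison, fry left 4 uncalled. These were secondary and tertiary granule (fry adjusted p = 0.0666), interferon (0.403), cell cycle (0.204) and immediate early genes (0.0666). The median and the mean differed in sign for the p53 list (-0.28 and 0.29) and the dendritic cell list (-0.04 and 0.27), and camera's direction for the T and NK cell list was down against a mean of 0.13. With the split of the control features as a block, the B cell list turned upwards (camera adjusted p = 0.0466).

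By fitted size the naming rule took Ddx4, F2r, Car1, Cpa3, Bex1, Hoxa9, Clca3a1 and Fabp7, a fatty acid binding protein, as the largest rises. All of them lay under 5.84 log2 units in Gr1Mac, so the background of each probe set entered its size and rank. Ddx4 was at least 82.2-fold, Bex1 67.8-fold, Clca3a1 40.9-fold and Fabp7 43.0-fold higher. Among the falls it took, Pla2g7, an enzyme that degrades platelet-activating factor, Ptgs2, the inducible cyclooxygenase, the histamine-inactivating enzyme Hnmt, Tex15 and Marcks lay under 5.84 in MN1. They were at least 37.2-fold, 10.6-fold, 9.84-fold, 19.5-fold and 24.9-fold lower, while Fos fell by 5.33 ± 0.34 log2 units (SE), Asprv1 by 5.17 ± 0.49 and Ifitm1 by 5.05 ± 0.37. Their limma adjusted p-values lay between 0.000480 for Tex15 and 0.00581 for Ptgs2. Irf8, a monocyte transcription factor, was not called at 2.07 log2 units lower (adjusted p = 0.0577 by limma), nor was Cebpa at 0.68 lower (0.209).

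The MN1 cells were sorted on GFP and the Gr1Mac cells on myeloid surface markers, so this comparison covers cell type and construct together. Bright control features separated both MN1 arrays and MN1VP16 array 1 from MN1VP16 array 2 and both Gr1Mac arrays. With that split as a block 914 genes were higher and 572 lower, and 31 of the 85 called genes of the naming rule lost their call. All 5334 called genes kept their direction with this block, with a median size of 1.43 log2 units before and 1.45 after, while the median SE went from 0.236 to 0.396. A gene with MN1VP16 arrays as far apart as MN1 and Gr1Mac could hardly be called, so the kept directions are no test of the split. Without MN1 array 2 the counts were 1519 and 899, and without MN1 array 1 they were 2015 and 1365.

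**Figure D1:**
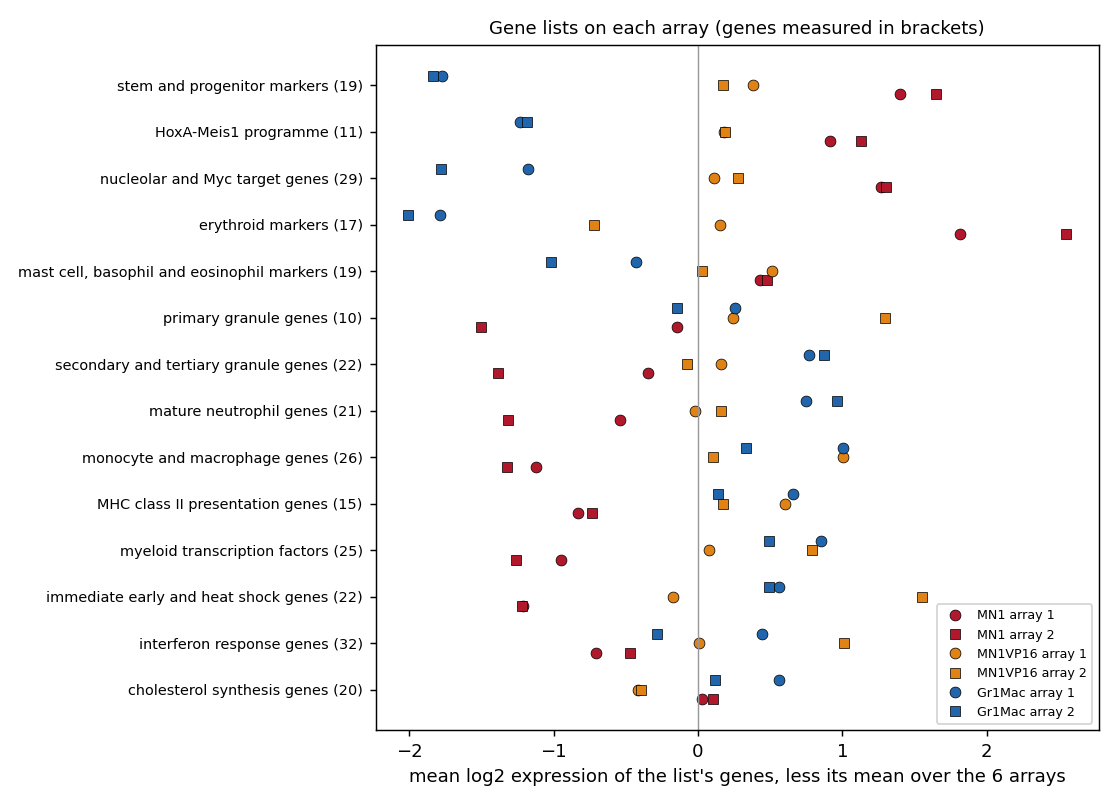
Mean log2 expression of 14 gene lists on each of the 6 arrays, less the list's mean over the 6 arrays; circles are array 1 and squares array 2 of MN1 (red), MN1VP16 (orange) and Gr1Mac (blue), and the number of measured genes is in brackets. Stem and progenitor markers lay at 1.40 and 1.65 on the MN1 arrays, 0.38 and 0.17 on the MN1VP16 arrays and -1.77 and -1.83 on the Gr1Mac arrays, and monocyte and macrophage genes at -1.12 and -1.33, 1.00 and 0.10, and 1.01 and 0.34.

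The second comparison asked how MN1VP16 cells differed from Gr1Mac cells. By camera, stem and progenitor genes, Myc targets and erythroid genes were higher as lists in MN1VP16 and cholesterol synthesis genes lower. With an estimated correlation none of these list calls held, but with 3 residual degrees of freedom hardly any list could. Fry called the stem and progenitor list (adjusted p = 0.00381) and no other list in this comparison. Its adjusted p was 0.0624 for Myc targets, 0.211 for erythroid genes and 0.0951 for cholesterol synthesis genes. Monocyte and class II genes were called in few members. The mast cell protease Cpa3 lay at 12.41 ± 0.10 (SD, n = 2) log2 units in MN1VP16 against 4.83 ± 1.07 in Gr1Mac, at least 95.4-fold higher (limma adjusted p = 0.00769). Hoxa9 was at least 30.7-fold, Cd34 21.3-fold and Gata2 23.6-fold higher, and the histamine-inactivating enzyme Hnmt was at least 9.84-fold lower. Limma called 666 genes higher and 384 lower, 573 and 321 of them by at least 2-fold.

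Stem and progenitor markers rose in 11 of 19 and fell in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 1.47e-10, and adjusted p = 0.119 with an estimated correlation). Kit at 1.08 ± 0.24 and Flt3 at 1.32 ± 0.69 log2 units higher were not called. In the HoxA-Meis1 programme, Hoxa9 rose and Hoxb4 was at least 2.80-fold lower (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.0249, and adjusted p = 0.559 with an estimated correlation), and Meis1 at 2.18 ± 0.67 higher was not called. That list lost its call without Gr1Mac array 1 (camera adjusted p = 0.233) or 2 (0.0533), and cell cycle genes, below, lost theirs without MN1VP16 array 2 (0.812) or Gr1Mac array 2 (0.310). Both lost it without the dimmest 40% of genes (0.0966), without genes whose highest group mean was under the median (0.117) and without probe sets marked _x_at, _s_at or _a_at (0.0648). Nucleolar and Myc target genes rose in 21 of 29 and fell in 0 (27 and 0 adjusted over the list alone; camera adjusted p = 5.49e-19, and adjusted p = 0.559 with an estimated correlation), led by the spermidine synthase Srm and the nucleolar protein Nop58, 6.83-fold and 6.68-fold higher. Erythroid markers rose in 8 of 17 and fell in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 4.43e-05, and adjusted p = 0.559 with an estimated correlation). Car1 was at least 20.6-fold and the claudin Cldn13 at least 7.86-fold higher. Cell cycle genes rose in 2 of 31, the licensing genes Mcm2 and Mcm3, also adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.843 with an estimated correlation). B cell markers rose in 3 of 21 (6 adjusted over the list alone), namely Vpreb1 and Igll1, the surrogate light chain of pre-B cells, and Dntt, which adds nucleotides during antigen receptor rearrangement (camera adjusted p = 0.000251, and adjusted p = 0.559 with an estimated correlation). The mean of that list was 6.09 on MN1VP16 array 1 and 6.90 on array 2, against 5.85 and 5.48 on the Gr1Mac arrays, so array 2 carried most of the rise.

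Cholesterol synthesis genes fell in 6 of 20 and rose in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 2.63e-06, and adjusted p = 0.559 with an estimated correlation), with the sterol oxidase Msmo1 4.84-fold and Hsd17b7 4.32-fold lower. Mature neutrophil genes fell in 3 of 21, Clec4d, Mxd1 and Samhd1 (13 adjusted over the list alone), and rose in Stfa3 and Stfa2l1, by 4.91 ± 0.30 and 2.83 ± 0.30 log2 units (camera adjusted p = 5.14e-05, and adjusted p = 0.559 with an estimated correlation). Among secondary and tertiary granule genes, 1 of 22 fell, Padi4, also adjusted over the list alone (camera adjusted p = 5.14e-05, and adjusted p = 0.690 with an estimated correlation). Myeloid transcription factors fell in 2 of 25, Junb and Nfe2 (3 adjusted over the list alone; camera adjusted p = 0.0185, and adjusted p = 0.559 with an estimated correlation). The myeloid factor call was lost without MN1VP16 array 1 (camera adjusted p = 0.532) or Gr1Mac array 1 (0.161). The other 13 lists were not called by camera, whose lowest adjusted p among them was 0.0864, for interferon response genes. Without MN1VP16 array 1, camera called interferon genes (1.41e-07) and primary granule genes (0.0115) higher, and monocyte genes (0.00150) and p53 target genes (0.0176) lower. Without Gr1Mac array 1 it called interferon genes higher (0.00158) and p53 target genes lower (0.0489), and without Gr1Mac array 2 monocyte genes lower (0.0327). The interferon list also passed narrowly with quantile normalisation (0.0497) and without probe sets marked _x_at, _s_at or _a_at (0.0451). Monocyte and macrophage genes had 1 rise, the mannose receptor Mrc1, and 1 fall, the complement chain C1qa, among 26 (1 and 2 adjusted over the list alone), and class II presentation genes 1 rise, H2-Ob, and 1 fall, Cd86, among 15 (2 and 2). H2-Aa lay at 10.72 ± 0.30 in MN1VP16 and 10.76 ± 0.06 in Gr1Mac, and Klf4 at 10.64 ± 0.42 and 10.32 ± 0.66.

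Elsewhere, T and NK cell markers had 1 rise, the interleukin-7 receptor Il7r at 4.38-fold or more, and 1 fall, Cd3d (2 and 1 adjusted over the list alone). Mast cell, basophil and eosinophil markers had 3 rises, Cpa3, Ms4a2 and Cyp11a1, and 0 falls (4 and 1). Megakaryocyte and platelet markers had 1 rise, F2r, and 3 falls, Clec1b, P2ry12 and Selp (2 and 3). P53 target and senescence genes had 1 rise, Cdkn1a, and 3 falls, Fas, Cdkn2d and Perp (1 and 6), and immediate early and heat shock genes 1 rise, Hsp90aa1, and 1 fall, Junb (2 and 2). Primary granule genes had 1 rise, Calr (2 rises and 1 fall), dendritic cell markers 1 fall, Cd209a (0 and 1), and stromal and endothelial markers 1 fall, Acta2 (0 and 1). Interferon response, chemokine and cytokine, and retinoid signalling genes had 0 calls, also adjusted over the list alone; the smallest p-values there belonged to Ifi47, Tap1, Tgfb1, Il18, Nrip1 and Rarg. Camera's direction differed from the sign of the mean for the immediate early list (down, mean 0.17), the megakaryocyte list (down, 0.28) and the chemokine list (up, -0.01), and the stromal list had a median of 0.01 and a mean of -0.08. Without MN1VP16 array 1 the immediate early list was called upwards (camera adjusted p = 0.000956), and without MN1VP16 array 2 downwards (camera adjusted p = 0.000245).

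Beside Cpa3 and Hoxa9, the largest rises by fitted size were those of F2r, Cd34, Gpam, Car1, Ddx4 and Gata2, all but Gpam with a Gr1Mac mean under 5.84 log2 units. Gpam, which starts glycerolipid synthesis, rose by 5.53 ± 0.53 log2 units (SE), and Ddx4 was at least 5.78-fold higher. Beside Hnmt, the largest falls included Tex15, Upp1, Krt86, Rps4l and the hyaluronan receptor Lyve1, which lay under that level in MN1VP16. They were at least 19.5-fold, 10.8-fold, 7.61-fold, 3.39-fold and 4.03-fold lower, while Pla2g7 fell by 4.08 ± 0.83 and Marcks by 3.54 ± 0.62. Their limma adjusted p-values ran from 0.00156 for Hnmt and Tex15 to 0.0473 for Pla2g7.

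These counts depended on Gr1Mac array 2, the Y-high array of that group. There, 22 genes were higher and 27 lower without it, and 1018 and 225 without Gr1Mac array 1 or with sex as a block. The split of the control features as a block gave 272 and 169, as did leaving out MN1VP16 array 1, and leaving out MN1VP16 array 2 gave 231 and 90. The fit on these 2 groups alone gave 181 and 166, as did leaving out either MN1 array. Of the called genes named in this comparison, Cpa3, Hnmt, Tex15, Lyve1, Il7r, Cd3d, Fas and Cd86 kept their call under each block, scaling and variance prior, with the mean of probe sets, without each array and with each filter on dim genes that left them in. Lyve1 (0.0113), Cd3d (0.0125), Fas (0.0113) and Cd86 (0.0113) had a limma adjusted p over 0.01, and the leaving out of marked probe sets and the test of every probe set were not followed for single genes.

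Many genes differed from Gr1Mac in the same direction in MN1 and in MN1VP16 cells; cell type and construct are not separated here either. There were 643 genes called higher and 364 called lower in both, and 0 in opposite directions. Independent lists of these sizes would share 115 and 46.2. Simulated unchanged groups with shared control arrays shared at most 1. With no change simulated hardly any gene is called, so that is no reference for lists of these sizes. Across genes, the differences of MN1 and MN1VP16 from Gr1Mac correlated at 0.82 (0.50 in the simulation, from the shared arrays alone) with a covariance of 0.616 (0.0357 simulated); genes are not independent replicates. After these results were seen, the Gr1Mac arrays were divided so that no array entered both differences. With Gr1Mac array 1 for MN1 and array 2 for MN1VP16 the correlation was 0.70 and 1030 genes were called in the same direction in both (150.8 for independent lists; 12 in opposite directions). The other way round it was 0.68 with 45 such genes (6.17 for independent lists; 2 opposite), as limma called only 49 genes in MN1VP16 against Gr1Mac array 1 alone. Without Gr1Mac array 2 the shared calls numbered 47, with an adjusted p under 0.01 they were 21, and leaving out any array other than Gr1Mac array 1 gave 381 or fewer. Of the 5334 genes called between MN1 and Gr1Mac, 4921 (92.3%) had an MN1VP16 mean between those groups. Over all 5334 the median position was 0.52 of the way from Gr1Mac to MN1. Choosing genes by the distance between those groups favours a mean between them, and no reference for this share was computed.

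The third comparison set MN1VP16 directly against MN1. By camera, monocyte, class II, myeloid transcription factor and immediate early genes were higher as lists in MN1VP16, and erythroid, stem cell and Myc target genes were lower. None of these list calls held with an estimated correlation, where 3 residual degrees of freedom let hardly any list pass. Fry called the stem cell list (adjusted p = 0.0233) and the class II, myeloid factor and erythroid lists (0.0484 each). It did not call the monocyte (0.0659), immediate early (0.118) and Myc target lists (0.0629). Except in the erythroid list, most members were not called. Klf4 was at least 27.9-fold higher (limma adjusted p = 0.00644), and the class II chain H2-Aa 20.4-fold (95% interval 14.2 to 29.3; 0.00400 by limma), from 6.37 ± 0.24 log2 units in MN1 to 10.72 ± 0.30 in MN1VP16 (SD, n = 2). Fabp7 was at least 43.0-fold lower (limma adjusted p = 0.00409), falling from 11.26 ± 0.41 to 4.23 ± 0.84, beside 3.88 ± 0.15 in Gr1Mac. Limma called 209 genes higher and 492 lower, 191 and 452 of them by at least 2-fold. The sex pattern given above differed completely between these groups, and with it as a block limma called 0 genes (2501 at an unadjusted p under 0.05, against 4091 without the block; lowest adjusted p 0.152). Over the 701 genes called without it, all 701 kept their direction with that block, the median size went from 1.60 to 1.57 log2 units and the median SE from 0.232 to 0.351. A gene with Gr1Mac arrays as far apart as MN1VP16 and MN1 could not be called, so the kept directions are no test of sex.

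Monocyte and macrophage genes rose in 8 of 26 and fell in 0 (20 and 1 adjusted over the list alone; camera adjusted p = 8.66e-12, and adjusted p = 0.382 with an estimated correlation). Irf8, which directs cells towards monocytes and away from neutrophils, rose by 3.49 ± 0.64 log2 units (SE), beside Klf4. Class II presentation genes rose in 4 of 15 and fell in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 7.97e-06, and adjusted p = 0.382 with an estimated correlation), namely H2-Aa, H2-Eb1 at 9.82-fold, the invariant chain Cd74 and H2-Ab1. Myeloid transcription factors rose in 7 of 25 and fell in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 3.40e-09, and adjusted p = 0.357 with an estimated correlation), with Jun 11.4-fold and Klf2 9.74-fold higher. Jun, Klf2, Junb, Nr4a1, Egr1, Fosb and Klf6 are also in the immediate early list, as is Klf4 from the monocyte list, so these lists are not separate evidence. The mean of the myeloid factors was 8.35 on MN1VP16 array 1 and 9.06 on array 2. Immediate early and heat shock genes rose in 6 of 22 and fell in 0 (13 and 2 adjusted over the list alone; camera adjusted p = 1.23e-07, and adjusted p = 0.391 with an estimated correlation), led by Klf4 and by Fos at 25.9-fold. The mean of that list was 9.16 on MN1VP16 array 1 and 10.88 on array 2, against 8.12 and 8.11 on the MN1 arrays. Fosb, Egr1 and the heat shock gene Hspa1a, named after their values were seen, lay at 4.74, 8.62 and 5.55 on MN1VP16 array 1 and at 9.68, 12.51 and 9.97 on array 2.

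Several further lists rose by camera although few or none of their members passed the test over all genes. Camera took a correlation of 0.01, while the estimate was 0.724 for interferon, 0.626 for primary and 0.898 for secondary and tertiary granule genes. Members that vary together thus counted as nearly separate evidence. Among these further lists fry called only chemokine and cytokine genes (adjusted p = 0.0484). Its adjusted p was 0.199 for interferon, 0.173 for primary and 0.186 for secondary and tertiary granule genes. Interferon response genes rose as a list with 0 of 32 members called, also adjusted over the list alone (camera adjusted p = 2.25e-08, and adjusted p = 0.425 with an estimated correlation), with means of 9.26 and 10.27 on the MN1VP16 arrays against 8.55 and 8.78; Ifit3 at 2.91 ± 0.59 and Cmpk2 at 1.36 ± 0.32 higher were nearest. Primary granule genes (0 of 10 called, adjusted p = 0.000152 by camera and adjusted p = 0.398 with an estimated correlation) and secondary and tertiary granule genes (0 of 22 called, adjusted p = 2.53e-07 by camera and adjusted p = 0.425 with an estimated correlation) had 0 calls adjusted over the list alone as well. The MN1 arrays were themselves apart there, at 11.26 and 9.90 for primary and 12.81 and 11.77 for secondary and tertiary granule genes. Mature neutrophil genes had 1 call among 21, Samhd1 (5 adjusted over the list alone; camera adjusted p = 6.13e-06, and adjusted p = 0.391 with an estimated correlation). B cell markers had 1 rise, the receptor chain Cd79a, and 1 fall, Ly6d, among 21 (10 and 1 adjusted over the list alone; camera adjusted p = 1.37e-05, and adjusted p = 0.388 with an estimated correlation). Their mean was 6.09 on MN1VP16 array 1 and 6.90 on array 2, against 5.56 on MN1 array 1 and less on array 2, so array 2 carried most of this rise. The B cell call was lost without the dimmest 40% of genes (camera adjusted p = 0.0507). Chemokine and cytokine genes had 1 rise among 24, Ccl2 (5 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.00209, and adjusted p = 0.357 with an estimated correlation).

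Erythroid markers fell in 10 of 17 and rose in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 3.80e-12, and adjusted p = 0.382 with an estimated correlation). Car1 was 10.1-fold and the erythroid transcription factor Klf1 9.21-fold lower than in MN1, and both stayed above Gr1Mac. Stem and progenitor markers fell in 5 of 19, Hlf, Tal1, Ikzf2, Adgrg1 and Kit, and rose in 1, Cd93 (11 and 1 adjusted over the list alone; camera adjusted p = 8.13e-07, and adjusted p = 0.261 with an estimated correlation). Hlf, a transcription factor of blood stem cells, fell by 3.19 ± 0.18 and Tal1 by 3.09 ± 0.57 log2 units, while Cd34 at 0.58 ± 0.56 lower, Flt3 at 2.72 ± 0.69 lower and Hoxa9 at 1.77 ± 0.58 lower were not called. Nucleolar and Myc target genes fell in 7 of 29 and rose in 0 (27 and 0 adjusted over the list alone; camera adjusted p = 7.37e-15, and adjusted p = 0.382 with an estimated correlation), with Myc 4.01-fold lower. Cholesterol synthesis genes fell in 3 of 20, the squalene epoxidase Sqle, Idi1 and Lss (5 adjusted over the list alone; camera adjusted p = 0.00268, and adjusted p = 0.425 with an estimated correlation). With sex as a block camera kept 12 of its 14 list calls here, losing the cholesterol (adjusted p = 0.871) and chemokine lists (0.0629). That block takes the sex difference from the Gr1Mac arrays alone, so the kept list calls are no test of sex either.

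The 9 lists left were not called, the lowest camera adjusted p being 0.0848 for the HoxA-Meis1 programme. Camera called that list lower without MN1VP16 array 1 (0.000362) or MN1 array 1 (0.0448), the megakaryocyte list lower without MN1VP16 array 1 (0.0119) and cell cycle genes lower without MN1VP16 array 2 (3.02e-05). The HoxA-Meis1 programme had 0 calls, as did cell cycle, megakaryocyte, and mast cell, basophil and eosinophil genes, also adjusted over the list alone; retinoid signalling genes had 0 calls too (2 rises adjusted over the list alone). P53 target genes had 1 rise, Cdkn2d, and 2 falls, Eda2r and Sesn1 (3 and 7), T and NK cell markers 1 rise, Klrk1 (1 and 1), dendritic cell markers 2 falls, Ccr9 and Ly6d (1 and 3), and stromal and endothelial markers 1 fall, Plvap (0 and 1). The median and the mean differed in sign for mast cell (0.05 and -0.19) and dendritic cell markers (0.09 and -0.18).

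Beside Klf4, Fos, H2-Aa, Jun and Irf8, the largest rises were those of Ms4a4c at 3.62 ± 0.38 log2 units (SE), the heparanase Hpse at 3.54 ± 0.47 and the lectin-like receptor Klrb1f at 3.45 ± 0.39. Beside Fabp7, the largest falls by fitted size included Lypd6b, the lipid phosphatase Plpp1, Pawr, Crhbp and Garem1, whose MN1VP16 means lay under 5.84 log2 units. They were at least 13.2-fold, 12.6-fold, 4.09-fold, 3.90-fold and 11.4-fold lower, while the collagen chain Col5a1 fell by 4.26 ± 0.59 and the transcription factor Sox6 fell by 4.10 ± 0.34. Among the called genes of the naming rule, H2-Aa, H2-Eb1, Fabp7, Plpp1, Pawr and Hlf lost their call with sex as a block. They kept it with the other blocks, each scaling and variance prior, each filter on dim genes that left them in, the mean of probe sets and without each array. Leaving out MN1 array 2 left 3 genes higher and 23 lower, MN1VP16 array 2 or the control feature split as a block 73 and 130, and MN1 array 1 252 and 224. Leaving out either Gr1Mac array left 104 and 350, and leaving out MN1VP16 array 1 163 and 335.

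Towards Gr1Mac, 659 genes lay back in MN1VP16: 474 genes higher in MN1 than in Gr1Mac were lower in MN1VP16 than in MN1, and 185 lower in MN1 were higher in MN1VP16. Independent lists would share 85.1 and 25.1. In the simulation of unchanged groups at most 1 was shared, which is no reference, since hardly any gene is called there. Across genes, the differences correlated at -0.83 (-0.50 in the simulation) with a covariance of -0.642 (-0.0359 simulated). The MN1 arrays enter both differences and were also divided afterwards. With MN1 array 1 against Gr1Mac and MN1VP16 against MN1 array 2 the correlation was -0.77 and 417 genes were called in opposite directions (31.2 for independent lists; 2 in the same direction). The other way round it was -0.77 again, with 24 such genes (2.77 for independent lists; 0 in the same direction) among 26 called in MN1VP16 against MN1 array 1 alone. Sex as a block left 0 of these genes, since it left 0 calls between MN1VP16 and MN1, and without MN1 array 2 there were 26, without MN1VP16 array 2 179, and without MN1VP16 array 1 or either Gr1Mac array between 425 and 430.

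**Figure D2:**
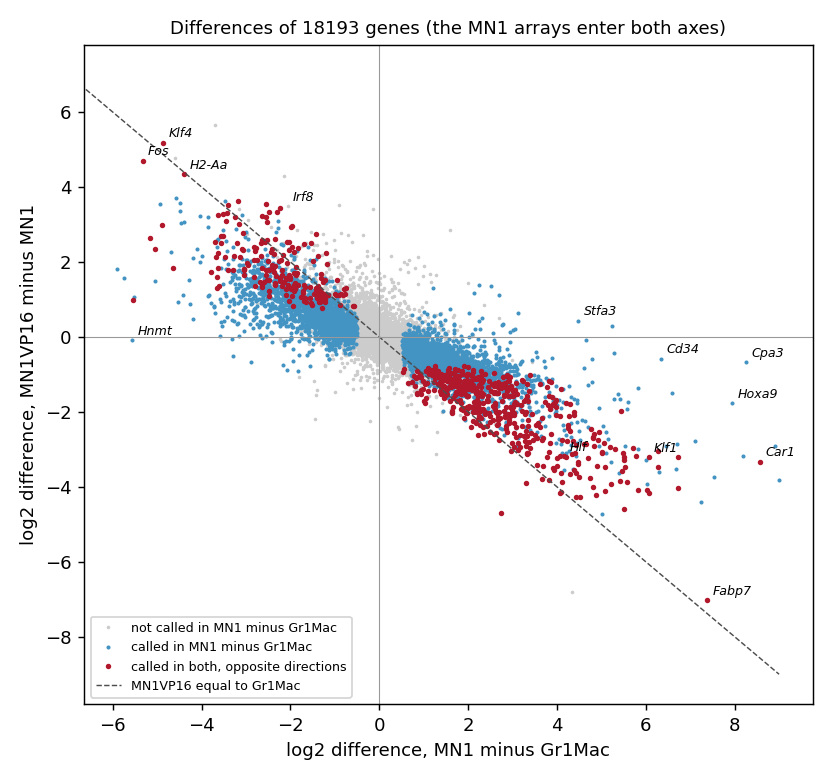
Log2 differences of 18193 genes, MN1 minus Gr1Mac on the x axis and MN1VP16 minus MN1 on the y axis (the MN1 arrays enter both); grey points were not called in MN1 minus Gr1Mac, blue points were, and red points are the 659 genes called in both with opposite directions, while on the dashed line MN1VP16 equals Gr1Mac. Fabp7, Klf4 and H2-Aa lay near the dashed line (MN1VP16 minus Gr1Mac 0.36, 0.32 and -0.04; Fabp7 with both means under 5.84), Stfa3 lay near a y value of 0 (0.43), and so did Hnmt (-0.09), whose MN1 and MN1VP16 means were both under 5.84.

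**Figure D3:**
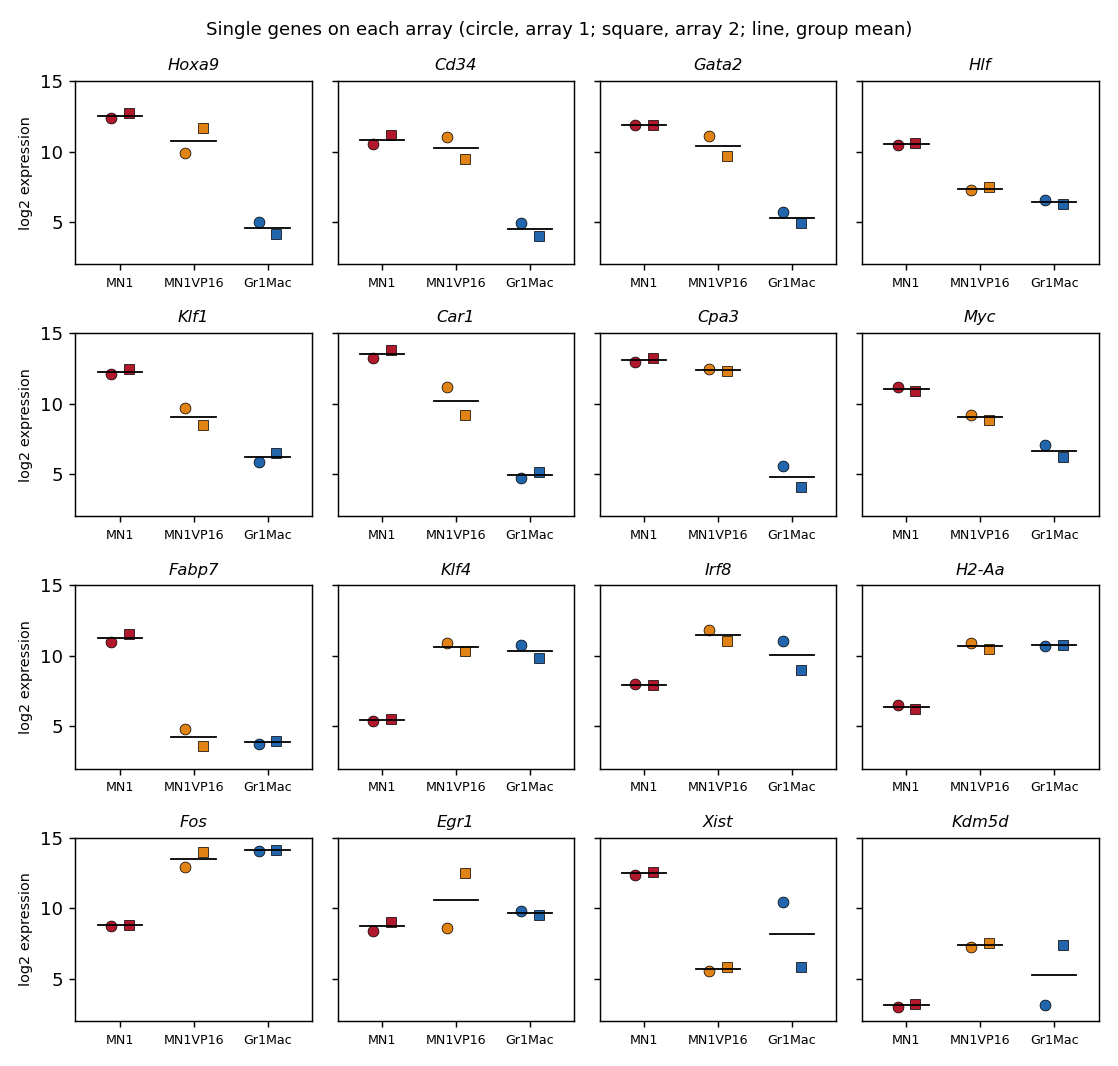
Log2 expression of 16 genes on each array (circle, array 1; square, array 2; line, mean of the group of 2). Hoxa9 and Cd34 lay between 9.50 and 12.71 on the MN1 and MN1VP16 arrays and between 4.00 and 5.02 in Gr1Mac, Klf4 lay at 5.36 and 5.56 in MN1 and between 9.85 and 10.93 elsewhere, and Xist and Kdm5d separated MN1 from MN1VP16 and divided the Gr1Mac arrays.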

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

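The tests reported here were run on values outside the comparisons or on patterns seen in them. The tests of the monocyte genes, the re-pairing test of the probe set names, the sex tests of the 2 differences from Gr1Mac and the tests with no array in both differences were chosen only after the result was seen. The other tests of the control feature split, the first test of the names and the sex test of MN1VP16 against MN1 had bounds written before their results were known. The intervals of slopes, shares and medians come from resampling genes, and that of a percentage counts genes as independent. They leave out the spread between arrays. For example, 1 share given below was 0.857 or 0.684 by which MN1 array was used.

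Control features, which no comparison used, divided the arrays across the groups. Among 24 control features with a mean over 8 and a range over 1 log2 unit, 16 had both MN1 arrays and MN1VP16 array 1 above MN1VP16 array 2 and both Gr1Mac arrays, by 1.60 log2 units on average. Others of the 24 separated the same arrays the other way, such as AFFX-BioB-5_at, AFFX-BioB-M_at and AFFX-PheX-5_at. The labels give no date or batch for these arrays. If such a batch caused the MN1 to Gr1Mac differences, the MN1VP16 arrays, which lie on both sides, would differ with a slope near 1 on them. The slope was 0.0400 (95% interval 0.0263 to 0.0531) over 5334 genes. The spread between the MN1VP16 arrays enters the call, however, so genes differing that much between them could hardly be called. This slope therefore cannot decide. Genes called with the MN1VP16 array across the split kept a median of 0.619 (0.585 to 0.642; 498 genes) of their difference from MN1 on the array within it, and of their difference from Gr1Mac 0.736 (0.650 to 0.796; 321 genes), but the MN1 or Gr1Mac arrays enter both differences there and the genes hold only 271 of 701 and 209 of 1050 called ones. With no array in both, the shares were 0.652 (196 genes) and 0.438 (0.410 to 0.471; 542 genes) against MN1, by which MN1 array was used, and 0.505 (0.460 to 0.538; 494 genes) against Gr1Mac, where limma called 0 genes the other way (4007 at an unadjusted p under 0.05). A batch as the whole cause needs shares near 0 where no array is in both, so it is argued against for the genes so tested. For the other called genes of MN1VP16, and for MN1 against Gr1Mac, it cannot be told apart from the group. With the split as a block, 1329 of 5334, 313 of 1050 and 145 of 701 calls were left. For both differences of MN1VP16 this block amounts to leaving out 1 MN1VP16 array. The median sizes were 1.45, 1.45 and 1.57 log2 units, from 1.43, 1.42 and 1.60. The median standard errors rose from 0.236, 0.217 and 0.232 to 0.396, 0.260 and 0.271. All called genes kept their direction, but a call needs arrays of a group close together. A gene that the block would turn round could thus hardly be called, and the kept directions and sizes do not weigh against a batch.

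The sex of the cells, read from Xist and 3 Y-linked genes, is not in the labels and divided the arrays otherwise. Over the 701 genes called between MN1VP16 and MN1, the Gr1Mac arrays, 1 of each pattern, differed with a slope of -0.0398 (95% interval -0.0577 to -0.0201). Sex as the cause needs a slope near 1. The spread between the Gr1Mac arrays enters the call, however, so a gene differing as much between them could not be called. Xist itself was not called, as given below. A slope near 1 was thus barred beforehand, and this slope cannot decide. Genes called in MN1 against Gr1Mac array 2 kept a median of 0.791 (0.781 to 0.802; 4732 genes, 4008 of the 5334 called) of that difference against Gr1Mac array 1, which shares the MN1 pattern, and with no array in both differences 0.857 (1117 genes) and 0.684 (0.674 to 0.692; 2658 genes). Those called in MN1VP16 against Gr1Mac array 1 kept 0.906 (0.792 to 0.973), but they were 49 genes, 42 of the 1050 called, and with no array in both limma called 0 genes (4007 and 4356 at an unadjusted p under 0.05), so for MN1VP16 against Gr1Mac sex cannot be told apart from the group. Sex as the whole cause is argued against for the genes tested between MN1 and Gr1Mac. For MN1VP16 against MN1, where sex and construct changed together, sex cannot be told apart from the group. With the block the 701 calls ended while the median size was 1.57 log2 units, from 1.60, and the median standard error rose from 0.232 to 0.351; the block also takes up a residual degree of freedom, and the shares of the 2 were not separated.

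Control features named for beta-actin and Gapdh had values that these abundant transcripts would not give. The highest of the 6 on any array was 3.77 log2 units, while the ordinary probe sets of Actb lay between 10.07 and 14.79, so ratios of 3' to 5' probe sets could not be used. If names and values were out of step in the ordinary probe sets too, probe sets of 1 gene would not vary together. In the first test, the smallest excess of their median correlation over that with names moved by 1 line, among 20 blocks of the table, was 0.0916, short of the bound of 0.2, so this test decided nothing; why moved names correlated in some blocks was not tested. In the second, 20 of 20 blocks had a median above the highest of 100 random re-pairings. The lowest block lay at 0.940, against a highest re-pairing of 0.778. Names moved by 1 line reached a block median of 0.854, so a shift by 1 line could pass this test in that block. Elsewhere the values argue against names out of step in the ordinary probe sets. The names of the control features stay unexplained.

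As lists, monocyte and class II genes were called higher in MN1VP16 than in MN1 by camera, with 8 of 26 and 4 of 15 members called by limma, but not with an estimated correlation (adjusted p = 0.382 for both), and the mix of cells in the GFP gate was not measured. A lower share of erythroid-like cells would raise the markers of all other types alike. The monocyte members exceeded the mast cell, basophil and eosinophil members by a median of 2.92 log2 units (95% interval 1.44 to 4.45, 19 and 6 genes with a mean over 7). They exceeded the secondary and tertiary granule members by 1.07 (0.123 to 1.67, 19 and 10 genes, also with a Gr1Mac mean under 14). Cpa3 and Ms4a2 of the mast cell list were themselves far higher in MN1 than in Gr1Mac, so that list need not mark cells apart from the erythroid-like ones. Granule genes averaged 12.81 and 11.77 on the MN1 arrays, so their rise depends on the MN1 array. These values therefore do not decide on a lower share of erythroid-like cells. More monocyte-like cells (61.1% of 18 abundant members, or 11, were over 1 log2 unit higher in both arrays, interval 35.7 to 82.7) and more neutrophils and monocytes alike (shares of the way to Gr1Mac differing by 0.329, interval -0.00229 to 0.524) cannot be told apart from each other or from higher expression per cell with these few genes. Each of these may contribute.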

How the results depend on the processing

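The blocks on the control feature split and on sex were added only after the results were seen; every other alternative was planned. Most alternatives moved at least 1 count of called genes by more than 1.5 times, and those counts follow; where no reason is given, the cause was not tested. In the order higher and lower in MN1 against Gr1Mac, in MN1VP16 against Gr1Mac and in MN1VP16 against MN1, then calls shared against Gr1Mac and genes that lay back towards Gr1Mac in MN1VP16, the counts were 3147, 2187, 666, 384, 209, 492, 1007 and 659. Every probe set on its own gave 5232, 4045, 1092, 808, 319, 819, 1804 and 1071, as it tests more features, and an adjusted p under 0.01 in limma gave 1726, 1021, 13, 9, 5, 22, 21 and 27. The control feature split as a block gave 914, 572, 272, 169, 73, 130, 380 and 182. Sex as a block gave 1018 and 225 for MN1VP16 against Gr1Mac, which amounts to leaving out Gr1Mac array 1, and 0 and 0 for MN1VP16 against MN1 in limma (2501 genes at an unadjusted p under 0.05), hence 0 lying back. The fit on the 2 groups of a contrast gave 181 and 166 for MN1VP16 against Gr1Mac, 104 higher for MN1VP16 against MN1, 337 shared and 422 lying back. For genes higher in MN1VP16 than in MN1, median centring gave 129 and leaving out genes whose highest group mean was under the median 323.

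Leaving out 1 array leaves a lone array that is assumed to vary like the other groups. It gave 1519 (without MN1 array 2) to 3103 (without Gr1Mac array 1) genes higher and 899 (without MN1 array 2) to 2097 (without either MN1VP16 array) lower in MN1 against Gr1Mac. For MN1VP16 against Gr1Mac it gave 22 to 1018 higher and 27 to 225 lower, each without Gr1Mac array 2 and without Gr1Mac array 1. For MN1VP16 against MN1 it gave 3 (without MN1 array 2) to 252 (without MN1 array 1) higher and 23 (without MN1 array 2) to 350 (without either Gr1Mac array) lower. Shared calls ran from 47 without Gr1Mac array 2 to 1193 without Gr1Mac array 1, and genes lying back from 26 without MN1 array 2 to 467 without MN1 array 1. In 0 of these settings was a gene called in the direction opposite to its call above. A call needs arrays of a group close together, so such a turn could hardly occur. The lists called by camera, 12, 10 and 14, ran from 10 to 12, 9 to 14 and 14 to 16. With an estimated correlation, and so on 3 residual degrees of freedom, camera called 0, 0 and 0, and fry called 10, 1 and 5. With the split as a block the interferon list in MN1 against Gr1Mac turned upwards (camera adjusted p = 0.262), as did the B cell list (0.0466), and the immediate early list in MN1VP16 against Gr1Mac was called upwards both with that block and without MN1VP16 array 1 (0.000956 in both), and downwards without MN1VP16 array 2; over the arrays left out its adjusted p ran from 0.000245 to 0.930 (without Gr1Mac array 1).

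Replicate numbers did not pair the arrays: deviations from the group means correlated at -0.0461, -0.0485 and 0.0804 between groups. The replicate number as a block gave 327 genes lower in MN1VP16 than in MN1, the only count it moved by more than 1.5 times, and left the call of all 23 lists as it was in each contrast.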

Other observations

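In a few genes MN1VP16 cells stood apart from both other groups. There were 11 genes called higher than in MN1 and than in Gr1Mac, where independent lists would share 7.65, and 6 called lower than in both, where they would share 10.4 (at most 1 and 0 in the simulation of unchanged groups). The MN1VP16 arrays enter both differences, so neither number is an exact reference for these counts. Tmem178 lay at 7.05 in MN1VP16 and, at a level that can be background, at 3.62 in MN1 and 3.76 in Gr1Mac. Cd93, a surface protein of early progenitors and endothelium, was 1.31 log2 units above MN1 and 2.51 above Gr1Mac. Acss2, which makes acetyl-CoA from acetate, was 2.47 log2 units below MN1 (-2.47) and 2.03 below Gr1Mac (-2.03), in the same direction as the cholesterol synthesis genes Sqle and Idi1. Cd24a was also below both (-0.99 and -1.48).

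Other genes had means close together with both constructs, by a bound on the difference of means and not by a test of likeness. Of the 1007 genes called in 1 direction in both against Gr1Mac, 389 had MN1VP16 within 0.5 log2 units of MN1, 169 of them higher and 220 lower than Gr1Mac. In 321 of these, 167 higher and 154 lower, both means were above 5.84 log2 units, the highest reading of Xist on the Y-high arrays; for the others the likeness can be that of background. Named after their values were seen, these included Mycn (5.29 in MN1 and 4.86 in MN1VP16 above Gr1Mac), the cell cycle kinase Cdk6 (2.57 and 2.49) and Gpam (5.25 and 5.53), with Stfa3. Gpam read 13.30 and 11.89 on the MN1VP16 arrays, further apart than the bound. Markers of several lineages were high together in the transduced cells: on the MN1VP16 arrays Cpa3, Hoxa9 and Cd34 were high beside Klf4 and H2-Aa, and arrays of bulk RNA do not tell whether single cells carried both.

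MN1VP16 array 2 stood apart from array 1 in genes that handling of cells also induces. Jchain, of plasma cells, lay at 5.92 on array 1 and 10.47 on array 2, next to the differences in Fosb, Egr1 and Hspa1a. Within the pairs, 510 genes in MN1, 904 in MN1VP16 and 755 in Gr1Mac differed by more than 1 log2 unit. Xist itself was not called between MN1VP16 and MN1 (limma adjusted p = 0.0527), although its arrays were completely separated.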
